A study of Mus musculus with 2 samples.

How the data were processed

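The series measured monomethylation of histone H3 at lysine 4 (H3K4me1) by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse limbs at embryonic day 12.5. H3K4me1 is a histone mark found at enhancers and beside active promoters. Per the labels, both samples are biological replicates of 1 group: replicate 1 pooled limbs of 88 embryos and replicate 2 those of 68 embryos, males and females together, and library fragments were 300 to 500 bp long. No second tissue, stage or treatment was part of the series, so every comparison was made between regions, genes or gene lists within the same libraries, and the difference between the replicates served as the measure of error.

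The authors deposited 4 lists of peaks on genome build mm10: 1 list for each replicate, 1 list called on both replicates together (the pooled list) and 1 list of replicated peaks. Per the file headers, each replicate's list was derived from that replicate's filtered alignments together with 1 further file (replicate 1) or 2 further files (replicate 2) whose content the headers do not state. Per the file headers, the replicated list was derived from both single lists and the pooled list. The rule that made a peak replicated, the aligner and the peak caller are not given in the sources used here. For each peak the authors deposited a fold enrichment, which is a linear ratio over the caller's own background estimate, as the peak caller wrote it. For each peak the authors also deposited significance as −log10 of a p-value and −log10 of a q-value. The lowest −log10 p in any list was 2.00, so that no listed peak had a p above 0.0099. All 142820 replicated peaks were found in the pooled list with the same ends and values, so their fold enrichment is that of the pooled call. Because peaks are listed only above the caller's threshold, an uncovered base is one without a listed peak, not one shown to lack the mark. The lists hold no read counts, so the sequencing depth is unknown and no interval that needs it is given. Its part in the difference between the lists of the replicates could not be tested.

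The replicated list was used for main values and each replicate's own list for a value per replicate, given as mean ± SD with n = 2. Chromosomes 1 to 19 and X were analysed. A single peak of replicate 1 lay on chromosome Y and was left out. The text files that describe the deposited files hold no measurements and were read only for what each list derives from. Genes came from GENCODE mouse release 21 on GRCm38, the assembly that mm10 names, with matching chromosome lengths, and sequence came from the same assembly. Window coverage was the percent of the 50 kb on each side of a gene start that lay under peaks, computed for 21728 protein-coding genes. A gene start was the outermost annotated start, so that enhancers farther away or deep inside long genes did not enter the window. Peaks were placed by their midpoint in promoter (within 1 kb of a start of a protein-coding or long noncoding gene), exon, intron or intergenic sequence. Shares were set beside those of 100 lists shifted by a random circular offset on each chromosome. Overlap of replicates was counted where at least 50% of a peak was covered by peaks of the other list.

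Before the data were examined, 16 gene lists, 18 motif sequences, the tests and the alternatives were fixed. The lists were limb patterning transcription factors, limb signalling genes, cartilage and bone genes, skeletal muscle genes, tendon and connective tissue genes, endothelial genes, blood cell genes, surface ectoderm and epidermis genes, Schwann cell and melanocyte genes, neural transcription factors, endoderm transcription factors, liver genes, heart genes, neuron genes, housekeeping genes and chemosensory receptor genes. A list's mean coverage was set against 10000 random lists of the same size, matched on the number of coding gene starts in the window (deciles, which ties reduced to 6 groups), in a two-sided permutation test with Benjamini-Hochberg adjustment over the 16 lists. Random members were drawn with replacement within a group, or without replacement where a list took over 25% of it. Limb transcription factors were compared with neural and endoderm transcription factors by a two-sided permutation test with 100000 resamples. Replicated peaks at most 3 kb apart were merged into domains, and the limb lists among genes nearest to the longest 1% of domains were tested by a two-sided Fisher's exact test. Motif rates in peaks were divided by those in flanks of equal width, 5 kb away and free of peaks, and then by the same ratio for the reversed motif as a control for base composition, with 95% intervals from 1000 bootstrap resamples of chromosomes. That control is incomplete where, leaving aside positions open to any base, only 1 of both forms can hold a CpG, and such motifs are named. The p-values describe genes in these libraries. Genes are not independent replicates, and windows of neighbouring genes overlap. Coverage at offsets from 5 kb upstream to 5 kb downstream of gene starts was counted in 100 bp steps.

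Most genes named in the text follow a rule fixed beforehand: a set of limb genes, the 20 genes of highest coverage more than 50 kb apart, the 3 highest and 2 lowest members of each list, the genes nearest to the 10 longest domains and the 5 genes differing most between replicates each way. Outside this rule, and chosen after their values were seen, are the other limb genes at long domains and the X-linked genes Bcor, Gpc3 and Pja1. The same holds for genes that hold or neighbour a named peak or domain (Nfix, Pxn, Pdgfrb and Hoxa7). It also holds for the genes differing most with equal covered bases (Cpa1, Cep41, Hoxc12 and Hoxc13). The alternatives were a −log10 q of at least 2, a fold enrichment of at least 3, the pooled list, each replicate alone, other overlaps, windows, promoter widths, merging distances, flanks and motif regions, counts of nearest peaks, 1 member per 200 kb and unmatched random lists. The alternatives with peaks touching both replicates, with autosomes alone and with equal covered bases were added after seeing the data.

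The gene list and transcription factor tests, replicate overlap, genomic distribution, distance, domains and motif counts were tested on simulated data, whereas chromosome density, coverage around starts, the correlation of fold enrichment and the replicate difference were not. For the gene list test on 21728 genes, with lists of 20 drawn from 200 changed genes, 4.0% of 200 unchanged lists passed an unadjusted p of 0.05, against 47.5% at a factor of 1.5, 93.5% at a factor of 2 and 98.0% at a factor of 3. For the overlap of 30000 simulated peaks made with 60.2% in common, 60.5% were found. The transcription factor test passed in 6.0% of 100 repeats with nothing added and in all repeats with 8 percentage points added. The gene list and transcription factor simulations shuffled coverage between genes. They leave out the likeness of neighbouring windows and do not give the error rate for lists with clustered genes. Runs of peaks placed at limb and other genes gave a domain odds ratio of 20.8, and random peaks 1.05. The random peaks lacked the clustering of real peaks, so they do not give the error rate for real domains. All planted sites of the 18 motifs were found. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.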

Results

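H3K4me1, the monomethylated form of lysine 4 on histone H3, was mapped by ChIP-seq in limbs of mouse embryos at day 12.5. At this stage digits are being laid down and cartilage condenses. The sample description names the limb without telling forelimb from hindlimb. The mark is found at enhancers, the distal sequences that drive tissue-specific transcription, and beside active promoters. A single group was profiled, with 2 biological replicates made from limbs of 88 embryos (replicate 1) and 68 embryos (replicate 2). The deposited values were lists of peaks with the authors' fold enrichment and significance for each peak. Read numbers were not part of the lists, so the depth behind each replicate is unknown. The series asked where in the genome the mark lies in this tissue, and the comparisons are therefore between regions and genes, with the difference between the replicates as the error.

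The strongest replicated peak in the genome lay in an intron of Ncor2, which encodes a nuclear receptor corepressor, on chromosome 5 from 125147016 to 125161657 (mm10), with a fold enrichment of 10.8. Introns of Zfp423 and Ski, which encode transcriptional regulators, held peaks of 10.3-fold and 10.2-fold, and an intron of Ngfr, the nerve growth factor receptor gene, one of 10.1-fold. Across the genome 142820 replicated peaks with a median width of 629 bp covered 123.3 Mb, which is 4.82% of called sequence. Replicate 1 had 207976 peaks over 92.7 Mb and replicate 2 had 215517 peaks over 127.1 Mb. The median widths were 303 bp and 385 bp and the median fold enrichments 3.05 and 3.08. Replicate 2 therefore covered more of the genome with a similar number of peaks.

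Of the peaks of replicate 1, 70.0% were covered over at least 50% of their length by peaks of replicate 2, against 5.20% after circular shifts. In the other direction the share was 46.7%, against 3.58% after shifts. Among the most significant 25% of peaks these shares were 95.1% for replicate 1 and 82.9% for replicate 2, and among the least significant 25% they were 50.2% and 22.2%. When 50% of both peaks had to overlap, the shares were 36.6% and 35.4%. Over 76200 matched peak pairs, fold enrichment had a Spearman rho of 0.574 and a Pearson r of 0.655 across peaks, which are not independent replicates. With pairs sharing any base, rho was 0.431. The median log2 ratio of replicate 2 to replicate 1 was 0.07 with an SD of 0.35 over pairs, and 89.5% of pairs lay within 1.5-fold. Of the replicated peaks, 85.0% touched a peak of both single lists, 11.4% touched replicate 2 only, 3.26% replicate 1 only and 0.368% neither. Across the 21728 coding genes, window coverage in the replicates had a Spearman rho of 0.986. Windows of neighbouring genes overlap, and this rho and that of fold enrichment measure different things.

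Introns held the largest share of the mark. The peak of highest fold near Tbx4, the hindlimb T-box gene, lay in its own intron on chromosome 11 from 85893427 to 85897346 with a fold of 7.44. Those near Gli3, Tbx5, Prrx1, Runx2 and Bmp7 also lay in the introns of these genes, whereas those near Sox9, Bmp2 and Pax3 were intergenic. Of all replicated peaks, 54.1% were intronic (replicates 54.8% ± 0.301, SD, n = 2), 30.0% intergenic (30.3% ± 0.847), 10.1% in promoters (9.05% ± 0.298) and 5.83% exonic (5.80% ± 0.249). Shifted lists had 41.9%, 51.5%, 2.55% and 4.02%, and each observed share lay outside the range of the 100 shifts. The share of peaks in promoters was thus 3.97 times that of shifted peaks, and the intergenic share 0.582 times. The median distance to a coding gene start was 40116 bp against 71166 bp for shifted lists. Peaks more than 10 kb from a start made up 73.1% (74.5% ± 0.679, n = 2), against 85.5%, and peaks over 500 kb away 2.28% against 11.7%.

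Among the 16 gene lists, those of genes that pattern and build the limb had the highest coverage around their starts. Limb patterning transcription factors had a mean window coverage of 24.8% (replicates 21.5% ± 4.00, SD, n = 2), 3.31 times that of matched random lists. All 41 members lay above the genome median of 4.69%, and 27 of 41 were among the highest 10% of coding genes. Members within the HoxA and HoxD clusters share much of their windows, so these are not counts of separate loci. With 1 member per 200 kb the ratio to random lists was 3.23. Lmx1b, which sets dorsal limb identity, reached 53.4%, Hoxa9 49.2% and the mesenchymal homeobox gene Prrx2 46.8%, while the lowest members were En1 at 6.28% and Tfap2b at 5.78%. Limb signalling genes reached 14.9% (13.2% ± 2.25), 2.41 times random lists, led by Bmp7 at 37.7%, the hedgehog receptor gene Ptch1 at 36.9% and Fgfr1 at 34.3%, with Dkk1 at 2.13% and Rspo2 at 1.90% lowest. Cartilage and bone genes reached 15.5% (13.5% ± 2.71), 2.43 times random lists, with Runx3 at 32.3%, Pth1r at 29.6% and Foxc1 at 28.9% above Snorc at 2.56% and Col11a1 at 2.25%. Each of these 3 lists had a two-sided permutation p of 0.0002, the smallest the random lists can give, and an adjusted permutation p of 0.0008 over the 16 lists. Genes are not independent replicates, and these p describe the libraries at hand.

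Tendon and connective tissue genes reached 14.1% (13.0% ± 2.57, n = 2), 2.33 times random lists, with an adjusted permutation p of 0.0064. Tcf7l2 at 41.8%, Col5a1 at 29.1% and Tcf4 at 22.5% led that list, and Col3a1 at 2.04% and the X-linked Tnmd at 0.231% were lowest. By number of nearest peaks the ratio was 3.84 for this list and 4.34 for cartilage and bone genes. Endothelial genes had a mean of 12.1% (10.6% ± 2.26), 1.86 times random lists, with an adjusted permutation p of 0.0491. That mean rested on Fli1 at 51.5%, Eng at 26.9% and Erg at 25.6%, since the median was 5.29%, with Tek at 2.96% and Emcn at 0%. The endothelial call was lost in replicate 1 alone, at 1.82 times random lists, and under 6 other settings, so it was not firm.

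The chemosensory receptor genes, olfactory and vomeronasal receptors of sensory neurons, were the only list whose mean passed the test on the low side. Their 1464 members had a mean coverage of 0.219% (0.196% ± 0.0409, n = 2), 0.0287 times random lists, with an adjusted permutation p of 0.0008, and 1287 of them had no replicated peak within 50 kb. These genes lie in clusters, and with 1 member per 200 kb 282 remained and the ratio was 0.0660. It was 0.00519 in the 10 kb window, 0.0490 in the 100 kb window and 0.0172 by number of nearest peaks, and the list passed the test in each case. Olfr221, Olfr70 and Olfr71 had the highest values of this list at 12.7%, 11.1% and 11%, whereas Vmn2r98 and Vmn2r99 were at 0%.

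For the other 10 lists the mean was not distinguishable from random lists in the 50 kb window. In the 10 kb window housekeeping genes were 1.78 times and surface ectoderm and epidermis genes 1.86 times random lists, and both passed the test. Schwann cell and melanocyte genes turned to 1.25 times there without passing. By number of nearest peaks blood cell genes turned to 1.94 times, Schwann cell and melanocyte genes to 1.94, liver genes to 1.18 and heart genes to 0.846, none passing. Skeletal muscle genes had 9.40%, 1.56 times random lists (adjusted permutation p = 0.156). Chrna1 at 28.3%, Des at 22.9% and Pax7 at 17.1% were highest and Myf5 at 1.99% and Ttn at 1.83% lowest. Surface ectoderm and epidermis genes had 9.40%, 1.48 times random lists (adjusted permutation p = 0.204). Grhl3 at 29.0%, Tfap2a at 18.2% and Tfap2c at 17.2% were highest and Trp63 at 0.773% and Krt5 at 0% lowest. Housekeeping genes had 10.5%, 1.35 times random lists (adjusted permutation p = 0.138). They ranged from Rplp0 at 29.8%, Eef2 at 21.9% and Rpl13a at 20.1% to Hprt at 1.47% and Psmb2 at 1.41%. Heart genes had 8.52%, 1.23 times random lists (adjusted permutation p = 0.448). Hand1 at 19.5%, Myl7 at 17.9% and Tnni3 at 12.9% were highest and Tbx20 and Ryr2 at 3.51% and 3.43% lowest. Liver genes had 4.38%, 0.631 times random lists (adjusted permutation p = 0.209), and blood cell genes 6.35%, 0.778 times (adjusted permutation p = 0.445). Apoa2 at 17.1%, Apoh at 13.1% and Tat at 7.42% were the highest liver genes and Cyp7a1 and Serpina1a were at 0%. Cd68 at 19.7%, Klf1 at 13.1% and Epor at 12.6% were the highest blood cell genes, and the globin gene Hbb-bt and the myeloid integrin gene Itgam were at 0%. Neuron genes had 5.67%, 0.752 times random lists (adjusted permutation p = 0.445), with Slc17a7 at 19.4%, Grin1 at 10.1% and Elavl3 at 9.38% above Dcx at 0.917% and Elavl4 at 0.363%. Schwann cell and melanocyte genes had 5.94%, 0.895 times (adjusted permutation p = 0.827), with Sox10 at 12.1%, Pmel at 10.6% and Mpz at 8.90% highest and Plp1 and Tyrp1 at 0%. In gene-dense windows the peaks behind a value often lay in a neighbour, as for Rplp0, whose strongest peak was in an intron of Pxn.

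**Figure D1:**
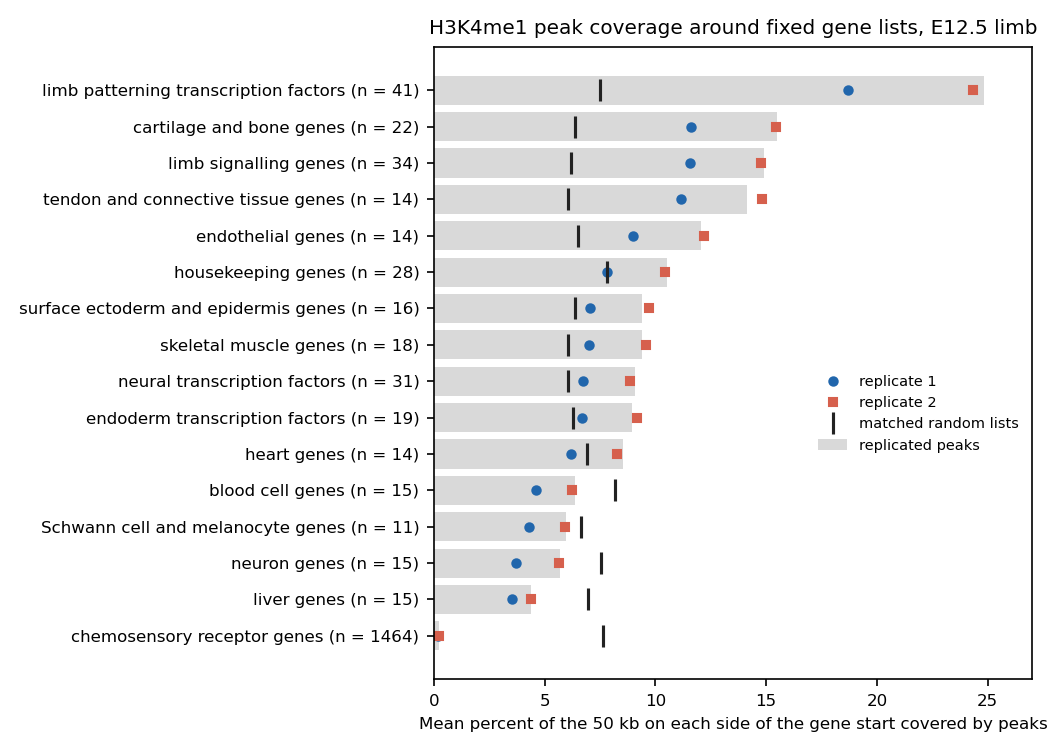
Mean percent of the 50 kb on each side of the gene start covered by H3K4me1 peaks, for the 16 gene lists. Grey bars are replicated peaks, circles and squares each replicate's own peaks, and black ticks the mean of matched random lists; limb patterning transcription factors lie highest at 24.8% and chemosensory receptor genes lowest at 0.219%.

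Neural transcription factors had a mean coverage of 9.06% (7.78% ± 1.5, n = 2; adjusted permutation p = 0.101) and endoderm transcription factors 8.93% (7.92% ± 1.78; adjusted permutation p = 0.204). Dlx1 at 19.9%, Dlx2 at 19.1% and Neurog1 at 18.2% were the highest of the neural list, and the forebrain genes Nkx2-1 and Foxg1 had 2.59% and 1.42%. Cdx1 at 24.5%, Barx1 at 14.8% and Foxa3 at 12.6% led the endoderm list, and the liver and gut regulators Foxa2 and Hnf4a had 3.35% and 2.60%. The strongest peak near Cdx1 lay closest to the start of Pdgfrb, a mesenchymal receptor gene. Against the 50 neural and endoderm factors together, at 9.01% ± 4.89 (SD over genes), the 41 limb factors at 24.8% ± 13.8 were higher by 15.8 percentage points, with a two-sided permutation p of 1e-05, the smallest the resamples can give. The difference was 12 points in replicate 1 and 15.4 points in replicate 2. Within 10 kb of the gene start, neural factors were 2.19 and endoderm factors 2.10 times random lists, and both lists passed the test in that narrow window.

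Coverage differed widely between single limb genes. Tbx4 had 42.7% (37.0% ± 6.05, SD, n = 2), Hoxd13 34.9% (29.9% ± 6.79) and Hoxa13 34.1% (28.2% ± 3.91), the last 2 being digit-forming Hox genes. The strongest peaks in these 2 Hox windows lay in exons of Hoxd9 and Hoxa7, 31797 bp and 42194 bp from the starts. Both values therefore take in other genes of the clusters. Prrx1 had 28.1%, the cartilage collagen gene Col2a1 27%, Hand2 25.1%, Gli3 24.3%, the hindlimb gene Pitx1 23.2%, Msx1 22.7% and the forelimb gene Tbx5 21.1%. Fgf8, the signal of the apical ectodermal ridge, had 19.6%, Bmp4 16.7%, the cartilage regulator Sox9 15.4%, Bmp2 13.3%, the joint gene Gdf5 13.2% and the muscle progenitor gene Pax3 11.3%. Lower values were found for Meis2 (9.31%), Runx2 (7.88%), Shh (7.16%), Fgf10 (4.5%), Acan (4.28%) and Grem1 (3.44%). Lmbr1 and Fmn1, the neighbours of Shh and Grem1, had 0.612% and 0.284% around their starts, and windows of 50 kb do not reach more distant regions. By number of peaks with the nearest start, Sox9 stood at 210 peaks, Gli3 at 97 and Bmp2 at 58, against 2 for Hoxd13, which lies among closely spaced Hox starts. Around Lmx1b, on chromosome 2 with its start at 33640511, the strongest peak spanned 33591223 to 33597041 in an intron with a fold of 7.98, and coverage was 42.3% in replicate 1 and 51.1% in replicate 2.

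**Figure D2:**
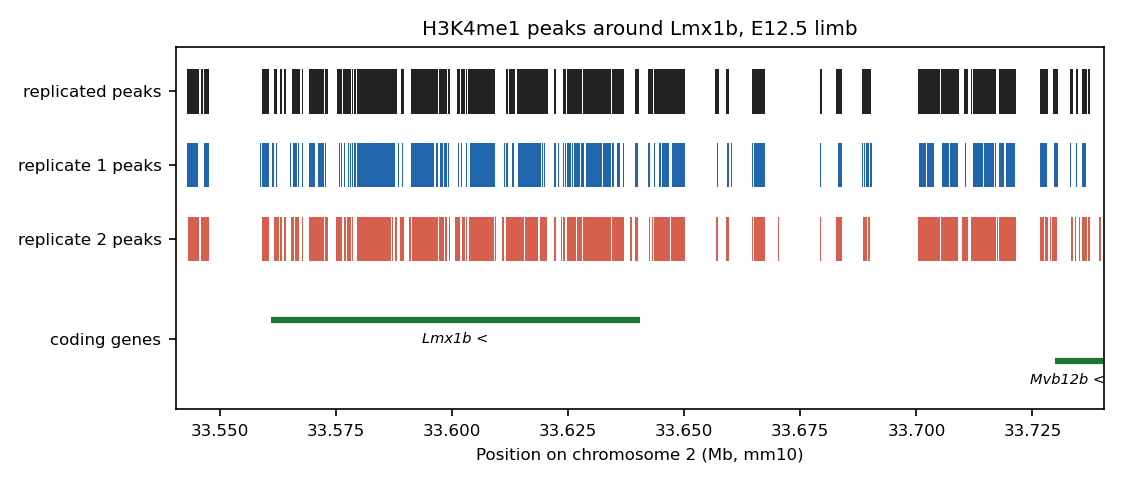
Map of H3K4me1 peaks within 100 kb of the Lmx1b start on chromosome 2 (mm10, x axis in Mb), with a row each for replicated peaks, replicate 1 and replicate 2, and coding genes below (the sign after each name gives the strand). A domain of 91204 bp spans the Lmx1b gene in the replicated list, and the region holds 60 replicated peaks, 102 of replicate 1 and 89 of replicate 2.

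Among coding genes more than 50 kb apart, window coverage was highest at Mrpl23 with 65.4% (60.8% ± 4.81, SD, n = 2), followed by Prdm16 at 63.2% (55.6% ± 5.34), G430095P16Rik at 60.2% and Hoxa5 at 59.6%. Gse1, Ncor2, Ccdc33, Flrt1, Ski and Bahcc1 had 55.0% to 56.6%. Dusp7, Igsf3, Zmiz1, Ahdc1, Ngfr, Tcf20, H2afy, Lmx1b, Nxn and Ssbp3 completed the 20 highest of these, with 52.6% to 54.6%. The strongest peak near Mrpl23 was intergenic, on chromosome 7 from 142568405 to 142575841, with a fold of 9.16. Of all coding genes, 18.1% had no replicated peak within 50 kb.

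Limb genes were over-represented beside the longest stretches of the mark, although most of these stretches lay near other genes. The longest domain spanned 121403 bp across the start of Ssbp3, a cofactor gene of LIM-homeodomain factors, on chromosome 4 from 106905076 to 107026478, and peaks covered 78.8% of it. The next longest had their midpoints in introns of Zfp423 (110530 bp), Nfix (103875 bp, nearest coding start G430095P16Rik), Tcf7l2 (95934 bp), Lmx1b (91204 bp), Shb (90234 bp), Cuedc1 (85806 bp), Prdm16 (84581 bp), Gse1 (82314 bp, nearest coding start Gins2) and Ror2 (82074 bp). The domains at Zfp423, Nfix, Lmx1b, Shb and Cuedc1 also crossed the starts of these genes. Among the 530 genes nearest to the longest 684 domains, 19 belonged to the limb lists (3.58%). Of the 14639 genes nearest to other domains only, 74 did so (0.505%). Genes nearest to no domain were left out. The odds ratio was 7.32, with a two-sided Fisher's exact p of 3.97e-10. The test was not matched on the span around each gene, and a gene with distant neighbours can be nearest to more domains. Whether part of the excess comes from this was not tested. These 19 genes were Bmp7, Cyp26b1, Fgfr1, Fgfr2, Foxc1, Gli3, Hand2, Hoxd10, Lhx9, Lmx1b, Msx2, Pitx1, Prrx2, Ptch1, Runx3, Sall1, Sox9, Spry4 and Tbx2. By list, these were 10 of 41 limb patterning transcription factors, 6 of 34 limb signalling genes and 3 of 22 cartilage and bone genes. Other lists also had members nearest to such domains, with 2 of 14 heart, 2 of 14 endothelial, 2 of 14 tendon and connective tissue and 2 of 16 surface ectoderm genes. Liver, housekeeping and skeletal muscle genes had 1 member each, and the neural, endoderm, blood cell, Schwann cell, neuron and chemosensory lists had 0. Single lists were not tested. The shortest of these domains was 19417 bp long.

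Across all coding genes the mark flanked the gene start more often than it covered it. Of all coding gene starts, 14.6% lay under a replicated peak, against 35.6% of positions 1100 bp downstream and 22.1% of positions 600 bp upstream. Housekeeping genes showed a deep gap, with 17.9% of starts covered and 75.0% of positions 1300 bp downstream, a difference between start and flank of -57.1 percentage points (-50.0 in replicate 1 and -57.1 in replicate 2). Among the 14 housekeeping genes without another coding start within 10 kb the difference was -28.6 points. The flank was the highest value at any offset within 3 kb, a choice that favours negative differences in lists of few genes. Limb patterning transcription factors had 36.6% of starts covered and a difference of -19.5 points, and endoderm transcription factors 52.6% and -26.3 points, so the gap was not particular to housekeeping genes. Neural transcription factors had 64.5% of starts covered and a difference of -3.23 points, which was 3.23 points with the pooled list and -6.45 in replicate 2 alone, so that no gap was resolved for them. Surface ectoderm and epidermis genes had the highest share of covered starts, 81.2%. Liver genes had 13.3% of starts covered and chemosensory receptor genes 0.137%.

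**Figure D3:**
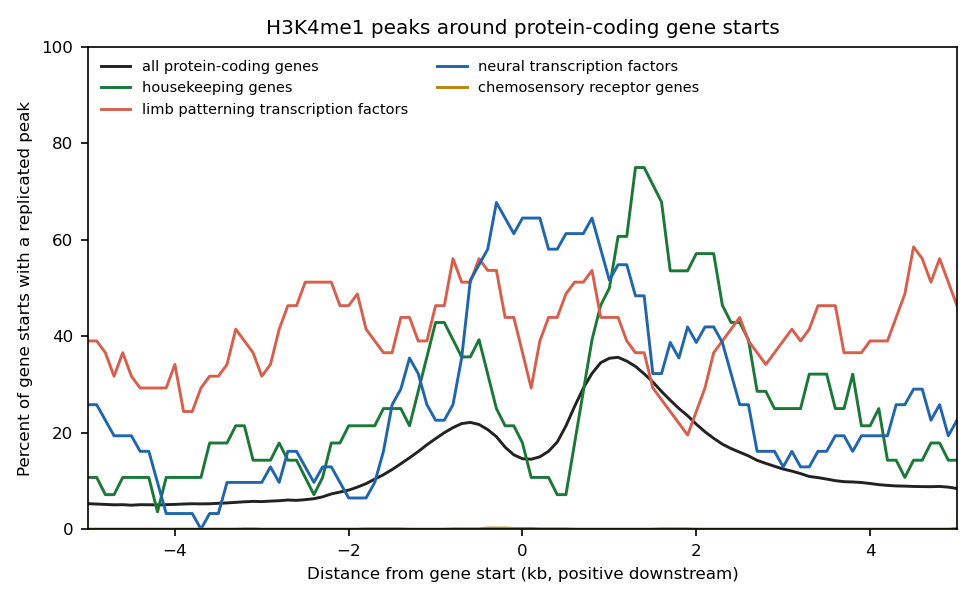
Percent of protein-coding gene starts with a replicated H3K4me1 peak at each offset from 5 kb upstream to 5 kb downstream, oriented by strand, for all coding genes and 4 gene lists (1 line each). Housekeeping genes rise to 75.0% downstream of a gap at the start, neural transcription factors are covered at the start, and chemosensory receptor genes stay near 0.

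Most of the 18 motifs had a higher ratio of peaks to flanks than their reversed forms, so this was not particular to regulators of limb mesenchyme. Of the 10 motifs for which neither form can hold a CpG, 8 had an interval above 1. The joint motif of TWIST basic helix-loop-helix and homeodomain factors, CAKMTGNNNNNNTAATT, had a ratio of 2.18 over its reversed form (95% bootstrap interval 1.74 to 2.85). The E-box bound by TWIST and HAND proteins, CAKMTG, had 1.67 (1.63 to 1.71), the HOX13 motif 1.4 (1.34 to 1.47), the SRF motif 1.38 (1.27 to 1.52), the TEAD motif 1.28 (1.22 to 1.34) and the homeodomain motif 1.25 (1.23 to 1.28). RUNX had 1.16 (1.13 to 1.19), GLI 1.15 (1.01 to 1.31), GATA 1.10 (1.06 to 1.14), MEIS 1.06 (1.03 to 1.09), AP-1 1.03 (1.01 to 1.05) and ETS 1.21 (1.05 to 1.41). For GLI the interval held 1 in the central 400 bp of peaks, and for ETS in replicate 2 alone. The intervals also held 1 for SOX (0.998), HNF4 (0.936), NFI (1.24), REST (0.842) and CTCF (0.835). They excluded 1 for NFI in the central 400 bp (3.08), for HNF4 (0.907), REST (0.751) and CTCF (0.564) with flanks 20 kb away, and for NFI (1.38) and REST (0.815) with the pooled list. REST also excluded 1 in replicate 2 alone (0.798). The TFAP2 ratio was 0.631 (0.575 to 0.691). Leaving aside positions open to any base, a CpG can occur in 1 form only of the E-box, the joint motif, HOX13, TFAP2, ETS, NFI, CTCF and REST, and for these the control for base composition is incomplete. Without that control 5 motifs were less frequent in peaks than in flanks, namely homeodomain at 0.853 times, RUNX at 0.978, GATA at 0.798, SOX at 0.700 and HNF4 at 0.970. The others ranged from AP-1 at 1.01 times to NFI at 3.13, with the joint motif at 1.28 and TFAP2 at 1.79.

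**Figure D4:**
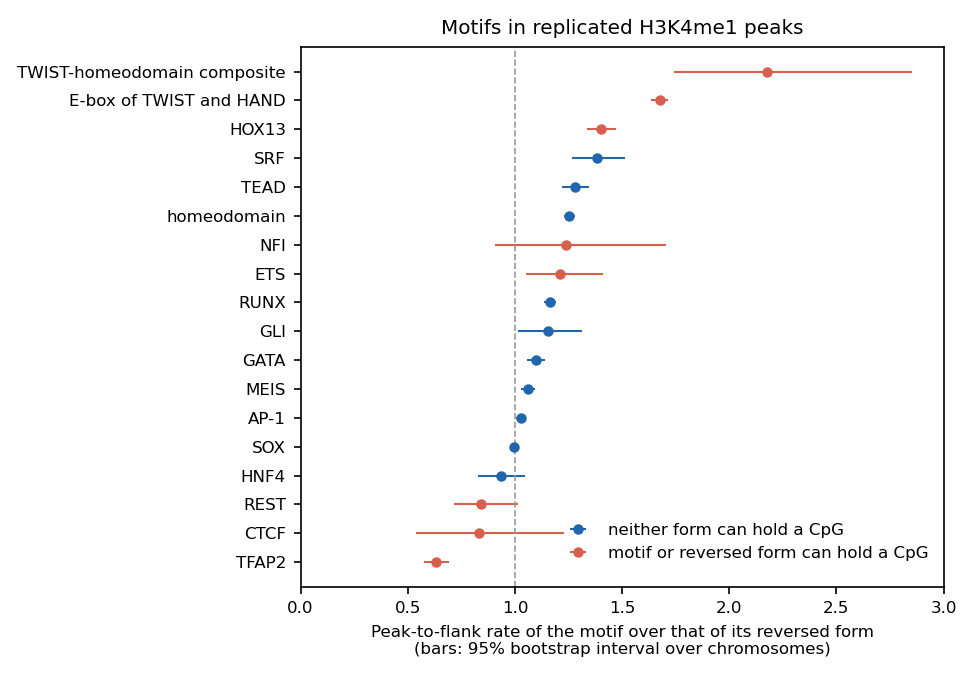
Ratio of motif rates in replicated peaks to flanks, divided by the same ratio for the reversed motif, for the 18 motifs (points, with bars for the 95% bootstrap interval over chromosomes). The joint TWIST and homeodomain motif lies highest at 2.18 and TFAP2 lowest at 0.631; red marks motifs for which a CpG can occur in the motif or its reversed form.

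Chromosome X carried few peaks. It had 5.02 replicated peaks per Mb, against an autosome median of 57.8 (49.0 to 82.9, highest on chromosome 11), a ratio of 0.0869 (0.0875 in replicate 1 and 0.104 in replicate 2). Peaks covered 0.335% of X and a median of 5.13% of autosomes. The median fold enrichment was 2.93 on X and 3.2 on autosomes. Among the genes named as the 2 lowest of their list, Tnmd, Plp1, Dcx and Hprt are X-linked. They were named for their low values, so they do not show where other X-linked members stood. Limb embryos of both sexes were pooled in each replicate.

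**Figure D5:**
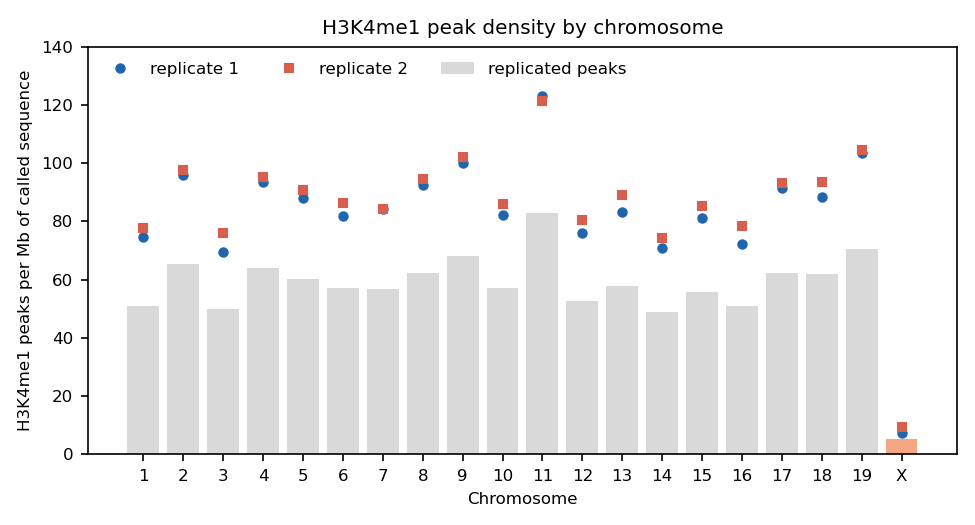
H3K4me1 peaks per Mb of called sequence on each chromosome, as bars for replicated peaks and as circles and squares for the peaks of replicate 1 and replicate 2. Autosomes lie between 49.0 and 82.9 replicated peaks per Mb and X at 5.02.

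With the same number of peaks taken from each, the replicates differed most around Tbx15, a T-box gene of skeletal development, where coverage was 24.1% in replicate 1 and 37.6% in replicate 2. Rai14, Wipf1, Hoxd9 and Hoxd10 were higher in replicate 2 by 11.9 to 12.9 percentage points. Krt86, Kcnab1, Anxa8, Ppp1r32 and the hair keratin gene Krt83 had the largest differences the other way, from -1.83 to -1.51 points. Replicate 2 was higher at 78.3% of coding genes, and its 207976 most significant peaks covered 125.0 Mb against 92.7 Mb for replicate 1. With equal covered bases, an alternative chosen after seeing the data, 42.0% of genes were higher in replicate 2 and 41.3% in replicate 1, with a median difference of 0. The largest differences were then 8.05 points at Cpa1 and 7.07 at Cep41, and the other way -5.67 points at Hoxc12 and Hoxc13. Hoxd9 and Hoxd10 then turned to -2.46 and -2.99 points, and Tbx15, Rai14 and Wipf1 stood at 1.42, 5.87 and 5.17 points, Ppp1r32 at -3.56 and Krt83 at -2.40. With 1 list per replicate, none of these differences could be tested.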

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

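The alternatives with peaks touching both replicates, with autosomes alone and with equal covered bases were chosen after seeing the data; the others were planned. Of the values recomputed, 349 kept their direction and side of the threshold or stayed within the replicate spread, 21 moved, 11 newly passed, 9 no longer passed and 10 reversed. Genomic distribution, distance to gene starts, the comparison of limb with neural and endoderm transcription factors and the limb genes at long domains kept their calls under all alternatives run for them; the last difference ranged from 12 to 20.8 (the highest in numbers of nearest peaks) and the odds ratio from 5.42 to 11. Limb transcription factors, limb signalling, cartilage and bone, tendon and chemosensory lists also kept their calls. Where a value changed, the cause was not tested unless stated. Depth is unknown, so what it limits could not be tested.

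The share of replicate 1 peaks found in replicate 2 was 73.7% with a −log10 q of at least 2, 77.7% with any shared base, 36.6% with 50% of both peaks and 69.3% with equal numbers of peaks; for replicate 2 peaks it was 43.6%, 62.5%, 35.4% and 47.7%. Rho of fold enrichment was 0.431 for pairs sharing any base. The endothelial list no longer passed with the pooled list (ratio to random lists 1.78), a fold of at least 3 (1.85), nearest peaks (2.01), unmatched lists (1.70), peaks touching both replicates (1.88), autosomes (1.78), or in 1 of the replicates alone (range 1.82 to 1.85). With the 10 kb window surface ectoderm (1.86), neural factors (2.19), endoderm factors (2.10) and housekeeping genes (1.78) newly passed, and Schwann cell and melanocyte genes turned to 1.25 without passing. By nearest peaks blood cell (1.94), Schwann cell and melanocyte (1.94), liver (1.18) and heart genes (0.846) turned direction, none passing on either side. The ratio of X to autosomes was 0.105 with the pooled list and 0.0875 to 0.104 in single replicates. Coverage of starts minus flanks was -17.0 points for all genes and -28.6 for housekeeping genes without near neighbours, and ranged in single replicates from -20.9 to -16.7 and from -57.1 to -50.0; for neural factors it was 3.23 with the pooled list and from -6.45 to -3.23 in single replicates. With equal covered bases 42.0% of genes were higher in replicate 2 and 41.3% in replicate 1, Hoxd9 turned to -2.46 and Hoxd10 to -2.99; this alternative takes only the most significant peaks of replicate 2, by construction. Among motifs, NFI excluded 1 with the pooled list (1.38) and the central 400 bp (3.08), REST with the pooled list (0.815), 20 kb flanks (0.751) and in 1 replicate (range 0.798 to 0.865), and HNF4 (0.907) and CTCF (0.564) with 20 kb flanks. GLI no longer excluded 1 in the central 400 bp (1.08), nor ETS in 1 replicate (range 1.19 to 1.22). SOX, near 1 throughout, turned to 1.00 with 20 kb flanks and ranged from 0.995 to 1.01 in single replicates.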

Other observations

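The comparison of limb with neural and endoderm transcription factors was planned. Its use here to weigh the type of locus was chosen only after its result was seen. The Fisher's exact test at gene starts, the Hox clusters and the X-linked genes described here were also chosen only after results were seen. The median fold of X peaks was known when the test of peak strength was set.

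The Hox clusters carried the mark unevenly. From the first to the last gene start, replicated peaks covered 57.6% of the HoxA cluster (replicates 50.6% ± 5.51, SD, n = 2), 49.5% of HoxC (41.1% ± 5.76), 43.4% of HoxD (37.5% ± 7.80) and 16.6% of HoxB (14.0% ± 4.43). The spans were not alike, with 171437 bp for HoxB against 94671 to 102564 bp for the other clusters, so the HoxB share describes a longer stretch. HoxA and HoxD hold genes that pattern the limb axis. HoxC was covered more than HoxD in replicate 1 (37.0% against 31.9%) and in replicate 2 (45.1% against 43.0%). Their replicate means differed by less than the SD of either cluster. On chromosome X, 612 of 948 coding genes (64.6%) had no replicated peak within 50 kb, against 16.0% of autosomal genes. The exceptions with the highest coverage were Bcor (23.0%), a corepressor gene, Gpc3 (19%), which encodes a proteoglycan of growth control, and Pja1 (16.7%). In replicate 1 a single peak lay on chromosome Y, with a fold of 2.73.

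Mean window coverage of X genes was 0.0905 of that of autosomal genes with matched local gene density (0.0785 in replicate 1 and 0.101 in replicate 2), which argues against low gene density as the cause. Peaks per Mb of sequence outside repeats gave a ratio of 0.107, so the larger repeat share of X (46.8% against a median of 33.4%) does not account for it either. The ratio also fell with the fold limit, as weaker enrichment that moves X peaks under the calling threshold would have it. It was 0.105 over all pooled peaks, 0.0635 at a fold of at least 3 and 0.00865 at a fold of at least 5 (6 X peaks), which is 0.0821 of the first. This cannot decide the question, because the lower median fold on X was known beforehand and the lists hold no values under the threshold. The cause of the few peaks on X stays open, since the single X of males, the inactive X of females and the unknown background behind the fold were not tested.

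For the high coverage around limb genes, 3 other properties of these loci were weighed. With 1 member per 200 kb, limb transcription factors remained 3.23 times random lists, which argues against repeated counting of Hox neighbours. Against random lists matched on GC content of the window they were at 2.60 times, so that base composition does not account for the whole difference. They were also 15.8 percentage points above other developmental transcription factors. That difference was known before it was used to weigh the type of locus, so no conclusion on the type of locus is drawn from it. A hypothesis that remains is that the mark follows genes in use in limb cells, which may be tested with expression data not used here. Housekeeping genes were 1.35 times random lists in the 50 kb window (adjusted permutation p = 0.138). In the 10 kb window they were 1.78 times, so these values do not settle it.

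Covered starts were found for 5 of 28 housekeeping genes (17.9%) and for 30 of 50 neural and endoderm transcription factors (60.0%), with a Fisher's exact p of 0.000362. That p cannot exclude chance because these lists were compared after their covered starts had been seen. Of all coding gene starts 14.6% were covered. The housekeeping share was thus not low beside all coding genes, and the transcription factors had the high share. Median GC content within 500 bp of the start was 57.2% for housekeeping genes and 59.9% for the transcription factors. The difference was -2.65 points (95% bootstrap interval -4.75 to 0.8). A higher GC content of housekeeping starts therefore does not account for their lower share than that of the transcription factors. Use of the lists in limb was not measured here, and lists of other tissues went both ways. Starts were covered for 13.3% of liver and 0.137% of chemosensory receptor genes, but for 35.7% of heart and 46.7% of neuron genes. No other histone mark was analysed here, and no biological explanation was tested.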
